A study of Mus musculus with 3 samples.

How the data were processed

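Single-cell RNA, 2 surface antibody tags (CD11c and Siglec-H) and 6 hashtags were measured in mouse spleen cells enriched for dendritic cells. Per the labels, leukemia-bearing or wild-type (WT) mice were given panobinostat, a histone deacetylase inhibitor, or vehicle for 2 days, spleen cells were put through a density gradient, a sort for GFP-negative cells and a magnetic negative selection, and 6 hashtagged samples were pooled for 1 capture with 10x 3' v3 chemistry. The 3 submitted samples are the gene expression, hashtag and antibody libraries of that capture. Per the file headers, the deposited matrix holds counts (whole UMI numbers per feature and barcode), with genes, antibody tags and hashtags together. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 3.1.0 were used with the mouse builds mm10 and GRCm38; the role and order of each tool are not given there. The matrix was used as deposited and no sequence was realigned. Positions were taken from the GENCODE vM21 annotation of GRCm38, in which 297 of 297 named genes were matched.

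The condition of each cell was read from the hashtag feature names, which carry a disease state, a treatment code and, for leukemia, a number: 2 leukemia vehicle samples (D5W, read as 5% dextrose in water), 2 leukemia panobinostat samples (LBH, read as panobinostat's development code LBH589), 1 WT vehicle and 1 WT panobinostat sample. The labels do not say whether the hashed samples are separate animals, so a p-value across them measures the spread between these hashed samples. A tag was called positive above the 99% point of a negative binomial distribution, fitted by maximum likelihood to the k-means cluster of barcodes with the lowest mean of that tag; a barcode needed exactly 1 positive tag. Of 38717 barcodes with 426901103 gene UMIs, 22164 (57.2%) had 1 tag, 14161 (36.6%) had several and 2392 (6.18%) had none. Barcodes with 500 or more genes and at most 10% mitochondrial UMIs (36904) were scored for doublets with a rewritten Scrublet score (simulated doublets among nearest neighbours); a score of 0.5 or more called 2169 of 20903 single-tag barcodes (10.4%) and 48.1% of those with several tags. After both filters 18734 cells with 160203000 UMIs were kept. Leukemia vehicle 2 had the lowest median count of its own hashtag in kept cells, 88 against 345 to 768 in the other samples. Under the ratio hashtag call described below, it had 1406 single-tag barcodes in place of 2937. WT panobinostat had 3202 in place of 3819, and the other samples had more.

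Cell numbers and median UMIs per cell differed between the hashed samples, which also differed in cell composition. In the order leukemia vehicle 1 and 2, leukemia panobinostat 1 and 2, WT vehicle and WT panobinostat, kept cells numbered 2619, 2662, 2424, 1637, 6249 and 3143, and median UMIs per cell were 5211, 13012.5, 5667, 5921, 5520 and 7584. Summed per class and sample, depth ran from 184850 UMIs (34 pDC-like cells, WT panobinostat) to 14557000 UMIs (cDC1-like). The common biological coefficient of variation was 5.54% in pDC-like, 6.70% in cDC1-like, 7.14% in cDC2-like and 8.70% in mature DC-like cells.

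Counts were scaled to the cell total and log-transformed. The 2000 most variable genes outside the fixed gene lists gave 30 principal components, a shared-neighbour graph (15 neighbours) and Leiden clusters at resolution 1 (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3; seed 1). A cluster took the class with the most markers raised, out of 17 marker sets plus a pancreatic acinar set. A marker was raised at a log2 fold of 1 or more over all other cells and 20 CPM or more. A name needed 3 or more raised markers, a mean marker log2 fold of 0.25 or more and within 0.1 of the best class, and no larger number of another class's markers among the 10 leading genes; a cluster with few UMIs also needed a marker of its own among them. Other clusters stayed unnamed. Names end in "-like" because they rest on RNA clusters alone.

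The 19 gene lists (307 genes), the marker sets, the comparisons, the tests planned for them, the thresholds and the rule for named genes were fixed before the data were examined. The camera tests of lists and the fits with an interaction term were not among those planned tests. The maximum-likelihood form of the hashtag fit, the doublet threshold, the conditions for naming clusters, the acinar markers, the share of DC-like cells as a denominator, 9 added alternatives and the use of the leukemia against WT coefficient as a comparison were set after the data were seen. DESeq2's independent filtering was switched off after it was found to shift 1 count between runs with different numerical libraries.

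Between classes, UMIs were summed per class, and the ratio of CPM was given with an exact conditional 95% interval, which covers counting error alone. A list member with 50 or more UMIs was called higher or lower when the interval excluded 1 and the ratio was 1.5-fold or more; the list median was placed among 10000 random lists matched on mean expression. In that rule, the genes named are the pair of members of each list with the largest ratio, without markers of the compared classes, with Ifnar1, Ifnar2, all histone deacetylases and every detected interferon gene in addition. Panobinostat was tested against vehicle per class on UMIs summed per hashed sample with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM, filterByExpr, quasi-likelihood F tests, disease state and treatment in 1 fit of 6 samples, two-sided, Benjamini-Hochberg adjusted p under 0.05. This comparison was to be run on condition that the files name each cell's condition, which the hashtag names do; shares per hashed sample were planned as values alone and were tested for the same reason. Named there are the 10 highest and 10 lowest log2 fold changes past the threshold and every list member past it. Genes given outside these rules are said to be so where they stand. Lists were tested with camera (fixed correlation, and estimated correlation as a second value), adjusted over the lists of each class and comparison. Shares of cells were tested with an exact two-sided permutation test of 3 against 3 samples, whose p cannot go under 0.1, adjusted over 16 tests. Fits with an interaction term tested whether the panobinostat change differed between disease states.

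The edgeR procedure was tested on simulated data with 200 changed genes per class. Counts were drawn from each gene's share of UMIs pooled over the samples, the real library sizes and the common dispersion of the class. Differences in dispersion between genes and differences with disease were not simulated, so recovery in the real data may be lower. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 31.3%, 79.1% and 100% in pDC-like, 68.7%, 82.1% and 97.0% in cDC1-like, 44.8%, 85.1% and 95.5% in cDC2-like and 38.8%, 73.1% and 100% in mature DC-like cells, with 3, 5, 11 and 4 calls among unchanged genes.

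Alternatives covered the filters on cells, doublets kept, Leiden resolution 0.5 and 2, 15 principal components, list genes used for clustering, the mean of per-cell CPM, thinning of cells, a minimum of 200 UMIs, a ratio hashtag call (top tag at 5 times the second), DESeq2 1.42.0, no filter on low counts and each hashed sample left out; added were a replicate block, leukemia samples alone, thinning to 2000 UMIs before edgeR, removal of named clusters and, between classes, edgeR with the hashed sample as a block. Cells without exactly 1 hashtag, called doublets and unnamed clusters were left out of the class comparisons, and no comparison was made for classes outside the 4 DC-like ones because of their small cell numbers. Results of some list members are not reported here. Figures were drawn with matplotlib 3.10.9.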

Results

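Spleen cells of 6 hashtagged mouse samples (2 leukemia vehicle, 2 leukemia panobinostat, 1 WT vehicle, 1 WT panobinostat) were profiled in 1 pooled capture, and 18734 cells with exactly 1 hashtag were kept (median 6078.5 UMIs). Dendritic cell-like (DC-like) cells fell into 4 classes. Plasmacytoid DC-like (pDC-like) cells, the DC type specialised in type I interferon secretion, made up 15.005% of kept cells (2811 cells, 95% interval 14.5 to 15.5%). They were led by Siglech, the gene of the surface lectin Siglec-H, with Klk1, Cox6a2 and Ly6d. Conventional DC1-like (cDC1-like) cells, the type specialised in cross-presentation to CD8 T cells, made up 16.1% (3020; 15.6 to 16.7%) and were led by Xcr1, a chemokine receptor, with Naaa and Cadm1. The cDC2-like cells, which present antigen mainly to CD4 T cells, made up 18.5% (3473; 17.98 to 19.1%). Mature DC-like cells, led by Ccr7, which guides DCs to T cell zones, and by Fscn1 and Ccl22, made up 19.7% (3692; 19.1 to 20.3%). Erythroid-like cells made up 6.11%, B cell-like 1.596%, and unnamed clusters 20.85%. Intervals give counting error within this 1 capture, and the shares follow the enrichment of the preparation. The cDC1-like share ranged from 11.4 to 18.3% and the mature share from 8.26 to 19.7% over the settings for filters and clustering.

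The antibody tags, which took no part in clustering, were read against these names. Median Siglec-H antibody counts were 457 UMIs in pDC-like cells and 239 to 246 in the other 3 classes, a ratio of 1.86 to the next class. Erythroid-like and B cell-like cells stood at 243 and 233, so the other 3 classes lay near the level of these non-DC cells. No such background was taken off the ratio. As a share of antibody UMIs (Siglec-H and CD11c together) the ratio was 3.05, which the lower CD11c counts of pDC-like cells also raise. Median CD11c counts, an integrin abundant on conventional DCs, were 2962 in cDC1-like, 2060 in cDC2-like, 1106.5 in mature and 384 in pDC-like cells. In each of the 6 hashed samples the Siglec-H median was higher in pDC-like cells (439 to 470.5) than in the other classes (232 to 249).

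Interferon-stimulated genes (ISGs), which type I interferon switches on through its receptor, were more abundant in pDC-like than in cDC1-like cells. Of 36 measured ISGs, 28 were higher in pDC-like cells, 3 lower and 5 within 1.5-fold, with a median log2 ratio of 1.68, at the 100th percentile of matched random lists. Ly6a, a surface protein induced by interferon, was 41.2-fold higher (95% counting interval 39.5 to 43.0), and Ifi27l2a 22.4-fold. Against cDC2-like cells the list was mixed: 16 of 39 higher, 11 lower and 12 within 1.5-fold (14 higher and 19 lower by edgeR with the sample as a block; median 0.22, percentile 60.3), with Ly6a 71.8-fold (66.1 to 78.0) and Ifi44 38.1-fold higher. In cDC1-like against cDC2-like cells 22 of 39 were lower and 5 higher (median −1.34), with Rtp4 at a ratio of 0.0204 and Ifit3b, an antiviral protein, at 0.0165.

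**Figure D1:**
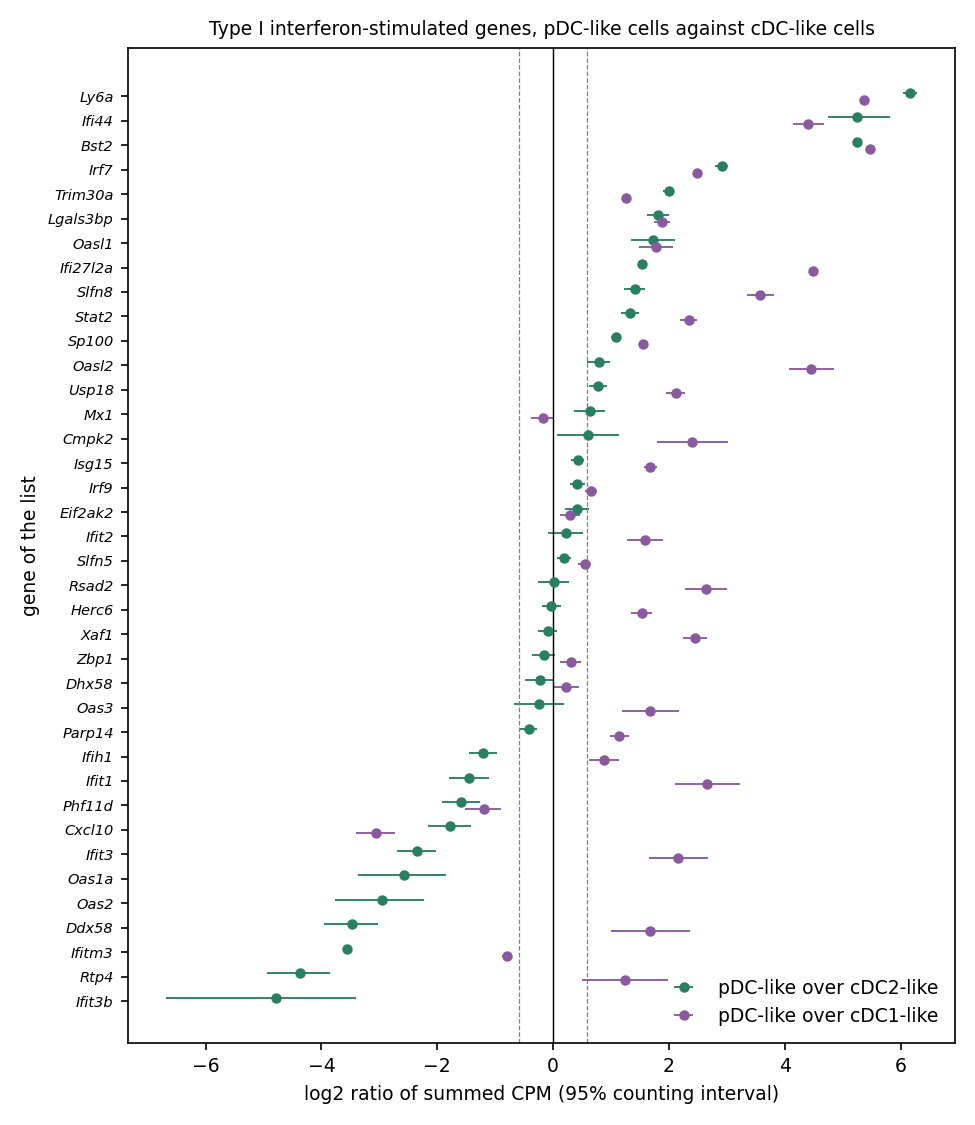
Log2 ratio of summed CPM of interferon-stimulated genes (1 member of the list is not shown) in pDC-like over cDC2-like cells (green) and over cDC1-like cells (purple), with 95% counting intervals and dashed lines at 1.5-fold. Ly6a, at the top, is 71.8-fold higher than in cDC2-like and 41.2-fold higher than in cDC1-like cells.

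Receptors and sensors of the interferon pathway were also unevenly held. Ifnar1 and Ifnar2, the subunits of the type I interferon receptor (chromosome 16, 91485238 to 91507441 and 91372783 to 91405589 in GRCm38), were 3.96-fold (3.62 to 4.34) and 3.77-fold higher in pDC-like than cDC2-like cells, and 4.74-fold and 6.35-fold higher than in cDC1-like cells. Ifngr1, a receptor subunit for interferon gamma, ran the other way, with ratios of 0.109 and 0.0709. Within the receptor and JAK-STAT list 7 of 12 members were higher and 3 lower in pDC-like than cDC2-like cells, 6 higher and 2 lower than in cDC1-like cells, and 3 higher and 5 lower in cDC1-like than cDC2-like cells, where the ratio of Ifnar2 was 0.593. Among genes of nucleic acid sensing, 8 of 18 were higher and 3 lower than in cDC2-like cells (7 and 6 by edgeR with the sample as a block), and 9 higher and 3 lower than in cDC1-like cells. They were led by Irf8 (33.4-fold over cDC2-like cells), a transcription factor of DC identity, and by Tlr7 (199-fold over cDC1-like cells, 129 to 322), the endosomal sensor of single-stranded RNA. In cDC1-like against cDC2-like cells 4 were higher and 5 lower, among them Irf8 at 17.1-fold and Tlr7 at a ratio of 0.0213.

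Transcripts of the listed interferons themselves were nearly absent. Of the 12 genes of the fixed interferon list, 2 had any UMI in kept cells, Ifng with 57 UMIs (3 in pDC-like cells) and Ifnz with 11 (0 in pDC-like cells). No UMI of a listed type I interferon gene was found in 2811 pDC-like cells, in vehicle and panobinostat samples alike. This leaves open transcripts below detection at a median of 5125 UMIs per cell. Interferon genes outside the list, such as other Ifna genes, were not counted. The ISG level varied between pDC-like cells: at 2000 UMIs per cell, 2780 cells held a median of 9 ISG UMIs (5th to 95th percentile 2 to 26, highest 62), a spread of 68.2% beyond counting error. Without Ly6a and Ifi27l2a, which held 42.0% and 22.2% of these UMIs, the spread was 103%.

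Lists of secretion and antigen presentation also divided the classes. Of 18 genes of the endoplasmic reticulum, 15 were higher in pDC-like than cDC2-like cells and 0 lower. Against cDC1-like cells 9 were higher and 0 lower (9 and 6 by edgeR with the sample as a block; percentile 93.3); Xbp1, the transcription factor of secretory capacity, was 5.75-fold (5.33 to 6.21) and 4.96-fold higher, and Hsp90b1, a chaperone, 4.62-fold. In cDC1-like against cDC2-like cells 10 of 18 were higher, with Creld2 at 2.87-fold. MHC class II genes were lower in pDC-like cells, 9 of 12 against cDC2-like and 8 against cDC1-like cells (2 higher), with Ciita, the regulator of class II transcription, at a ratio of 0.217 and H2-Ob at 0.113. In cDC1-like against cDC2-like cells 1 was higher and 3 lower. MHC class I genes were higher in pDC-like than cDC2-like cells in 6 of 13 (H2-K1 2.26-fold), and higher in 5 and lower in 3 against cDC1-like cells. They were higher in 6 in cDC1-like against cDC2-like cells (Pdia3 2.50-fold and Tap1, the peptide transporter, 2.33-fold).

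Most costimulatory genes stood lower in pDC-like than cDC2-like cells, and most chemokines and cytokines lower than in both other classes. Of 12 costimulation genes 8 were lower and 3 higher than in cDC2-like cells, with Cd80 at a ratio of 0.0282. Against cDC1-like cells 5 of 13 were lower, 3 higher and 5 within 1.5-fold. Between cDC1-like and cDC2-like cells 4 were higher and 6 lower. Of the chemokines and cytokines 11 of 14 were lower and 2 higher than in cDC2-like cells (Il1b 0.0289, Ccl5 0.133). Against cDC1-like cells 10 of 15 were lower and 2 higher (Cxcl9, which attracts T cells, 0.0242). Cxcl9 was 9.01-fold (8.53 to 9.54) higher in cDC1-like than cDC2-like cells, where 7 of 14 were higher and 4 lower. Cytokine and chemokine receptors were higher in 7 and lower in 5 of 15 against cDC2-like cells (Cxcr3 35.8-fold, Il7r 29.1-fold). They were higher in 9 and lower in 2 of 14 against cDC1-like cells (Il7r 281-fold, 205 to 395). Between cDC1-like and cDC2-like cells 3 of 15 were higher and 5 lower.

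The enzymes that panobinostat inhibits were present in all 3 classes. Of 11 histone deacetylases, 3 were higher (Hdac5 2.96-fold, Hdac9 2.10-fold, Hdac3 1.98-fold), 1 lower (Hdac4 0.401) and 7 within 1.5-fold in pDC-like against cDC2-like cells. Against cDC1-like cells 5 were higher and 0 lower, led by Hdac5 at 7.29-fold (6.21 to 8.59), Hdac10 at 2.80-fold and Hdac7 at 2.79-fold. Between cDC1-like and cDC2-like cells 1 was higher and 4 lower. Among matched random lists the median of pDC-like cells stood at percentile 45.7 against cDC2-like and 40.8 against cDC1-like cells. For cDC1-like against cDC2-like cells it stood at percentile 77.4. As a list the deacetylases therefore did not stand apart from genes of like expression in these comparisons. Acetyltransferases and acetyl-lysine readers were higher in 3 and 8 of 13 and lower in 1 and 1 against cDC2-like and cDC1-like cells, and 5 were lower in cDC1-like than cDC2-like cells. Genes known to rise with deacetylase inhibition were higher in 4 and lower in 5 of 13 against cDC2-like cells, higher in 6 and lower in 3 against cDC1-like cells, and lower in 5 in cDC1-like against cDC2-like cells.

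The remaining lists separated the classes as follows. Transcription factors of DC lineages were higher in 6 and lower in 13 of 20 in pDC-like against cDC2-like cells (Zbtb46, a factor of conventional DCs, 0.0505). They were higher in 10 and lower in 7 against cDC1-like cells (Zeb2 116-fold, Id2 0.04999), and higher in 3 and lower in 10 in cDC1-like against cDC2-like cells (Irf4 0.0470). Endocytic receptors were lower in 7 of 11, 6 of 9 and 6 of 13 and higher in 3, 2 and 4, with Ly75, a receptor for antigen uptake, 6.82-fold higher in cDC1-like than cDC2-like cells. Apoptosis genes were lower in 6 of 15, 7 of 16 and 3 of 16 and higher in 1, 2 and 6 (Bcl2a1b 0.0337 in pDC-like over cDC2-like cells). Glycolysis genes were lower in 3, 7 and 2 of 12 and higher in 0, 0 and 4. Immediate early and stress genes were lower in 11, 9 and 10 of 15 and higher in 0, 2 and 0 (Atf3 0.0306 in pDC-like over cDC2-like cells). Cell cycle genes were lower in 18 and 24 of 24 in pDC-like against cDC2-like and cDC1-like cells. With list genes used for clustering, Rrm2 (log2 ratio 0.21) and Cenpf (0.55) reversed against cDC1-like cells. In cDC1-like against cDC2-like cells 16 were higher (Rrm2 6.11-fold, Ccna2 5.22-fold), but this call turns with the placing of cycling cells: the log2 ratio of Rrm2 was −0.46 and that of Ccna2 −0.70 at Leiden resolution 0.5. In the main clustering 488 cells with Pclaf and Top2a among their leading genes had most raised markers from the cDC2 set. That cluster stayed unnamed and was left out of cDC2-like cells, while a cDC1-like cluster with Pclaf among its leading genes was kept.

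The calls above rest on counting error within the pooled capture. With edgeR and the hashed sample as a block, a test across samples added after the data were seen that calls changes of any size, several lists divided otherwise. In pDC-like against cDC2-like cells 14 ISGs were higher and 19 lower of 39, 7 and 6 genes of nucleic acid sensing of 18, 3 and 4 acetyltransferases and readers of 13, 6 and 5 genes known to rise with deacetylase inhibition of 12, and 7 and 7 cytokine and chemokine receptors of 15. Against cDC1-like cells 9 genes of the endoplasmic reticulum were higher and 6 lower of 18, 5 and 3 histone deacetylases of 11, 5 and 7 MHC class I genes of 13, 6 and 5 interferon receptor and JAK-STAT genes of 12, and 10 and 10 DC transcription factors of 20. In cDC1-like against cDC2-like cells 8 genes of nucleic acid sensing were higher and 6 lower of 17, 7 and 4 MHC class II genes of 12, and 4 and 4 histone deacetylases of 11. Of the ISGs against cDC1-like cells 26 were higher and 5 lower of 35 (28 and 3 of 36 above), and of the genes of the endoplasmic reticulum against cDC2-like cells 16 and 1 of 18 (15 and 0 above). Over the named list genes, where the block test was also held to a change of 1.5-fold or more, 126 kept the call, 7 lost it and 4 gained one.

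With panobinostat, pDC-like cells took up a smaller share of DC-like cells in both disease states. The permutation test that was run, which does not take disease state into account, cannot establish this difference. No test of shares with disease state was run. The shares were 50.9 and 34.2% in the leukemia vehicle samples, 23.3 and 13.04% in the leukemia panobinostat samples, and 14.2% and 1.96% in WT vehicle and panobinostat (vehicle mean 33.1 ± 18.3%, panobinostat 12.8 ± 10.7%, SD, n = 3 each). The panobinostat over vehicle ratio was 0.428 in leukemia and 0.138 in WT (two-sided exact permutation p = 0.2, adjusted p = 0.64; with 3 against 3 samples this p cannot go under 0.1). Of all kept cells the shares were 43.5, 11.4, 20.1, 9.59, 11.0 and 1.08% in the same order (exact permutation p = 0.4, adjusted p = 0.8). The share of DC-like cells was chosen as a denominator after unnamed and erythroid-like clusters were seen to fill 50.2% and 15.3% of leukemia vehicle 2. The cDC2-like share of DC-like cells was 1.94 times as high with panobinostat in leukemia and 0.734 times in WT (exact permutation p = 0.3, adjusted p = 0.8), the mature share 1.57 and 1.13 times (exact permutation p = 0.2, adjusted p = 0.64), and the cDC1-like share 0.845 and 1.67 times (exact permutation p = 0.8, adjusted p = 0.9).

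**Figure D2:**
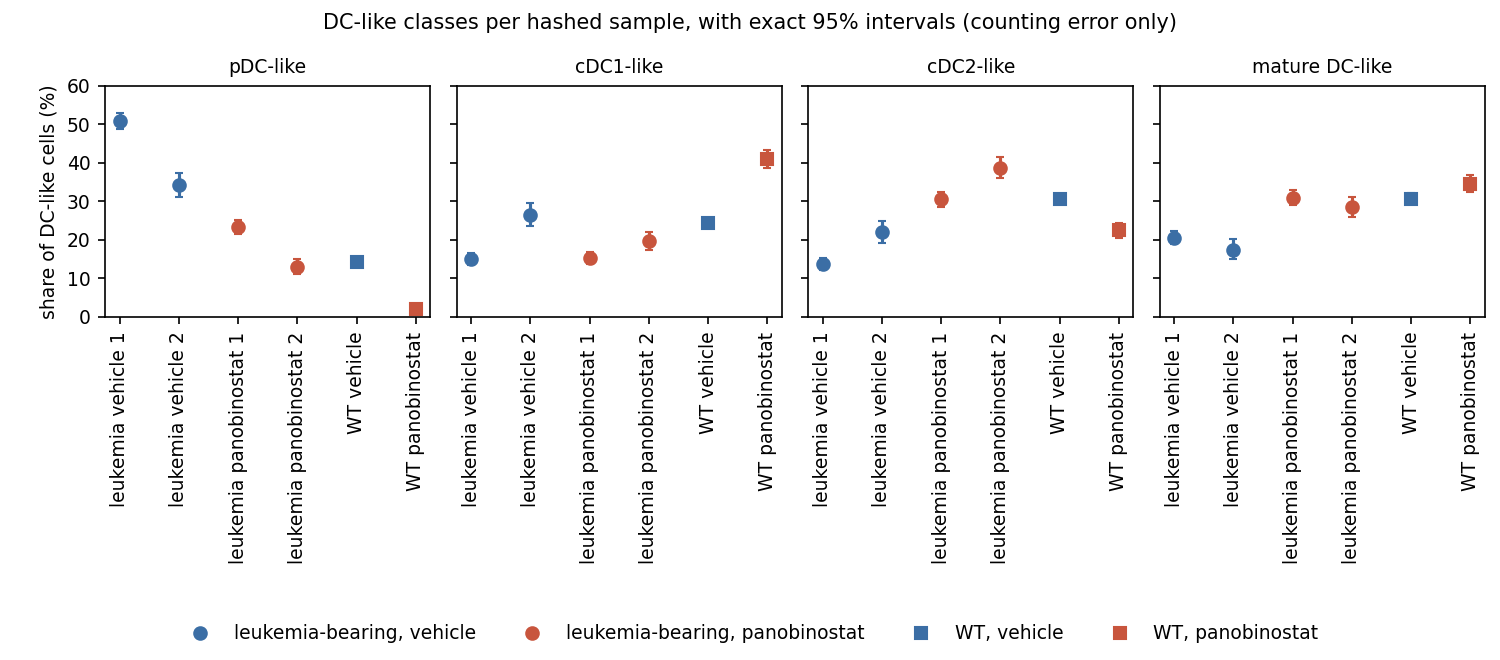
Share of DC-like cells (%) in each class, 1 point per hashed sample with exact 95% counting intervals; blue is vehicle, red panobinostat, circles leukemia-bearing and squares WT. The pDC-like share is 50.9 and 34.2% against 23.3 and 13.04% in leukemia, and 14.2% against 1.96% in WT.

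Cell cycle genes rose with panobinostat in cDC1-like cells. Of 24 measured S and G2/M genes 19 rose and 0 fell (22 rose adjusted over the list alone), and all 24 had a positive log2 fold change (median 0.58). Rrm2, the ribonucleotide reductase subunit that supplies DNA synthesis (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146), rose by 0.92 (SE 0.14, edgeR adjusted p = 0.0011), and Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361), by 0.63 (SE 0.094, adjusted p = 0.0011). Pcna, the clamp of the DNA polymerase, rose by 0.57 (adjusted p = 0.0014). The list moved up by camera (adjusted p = 6.8e-33), and adjusted p = 0.453 with an estimated correlation. The cycling cluster held 17.4 and 19.6% of cDC1-like cells in leukemia vehicle, 18.5 and 23.6% in leukemia panobinostat, 8.37% in WT vehicle and 22.9% in WT panobinostat samples. Without that cluster 10 of the genes rose (median 0.46), in the leukemia samples alone 7 (median 0.43, 20 of 24 positive), after thinning to 2000 UMIs 3 (median 0.52) and by DESeq2 11 (median 0.56). With 1 hashed sample left out 9 to 22 rose, and without either WT sample 1 fell.

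**Figure D3:**
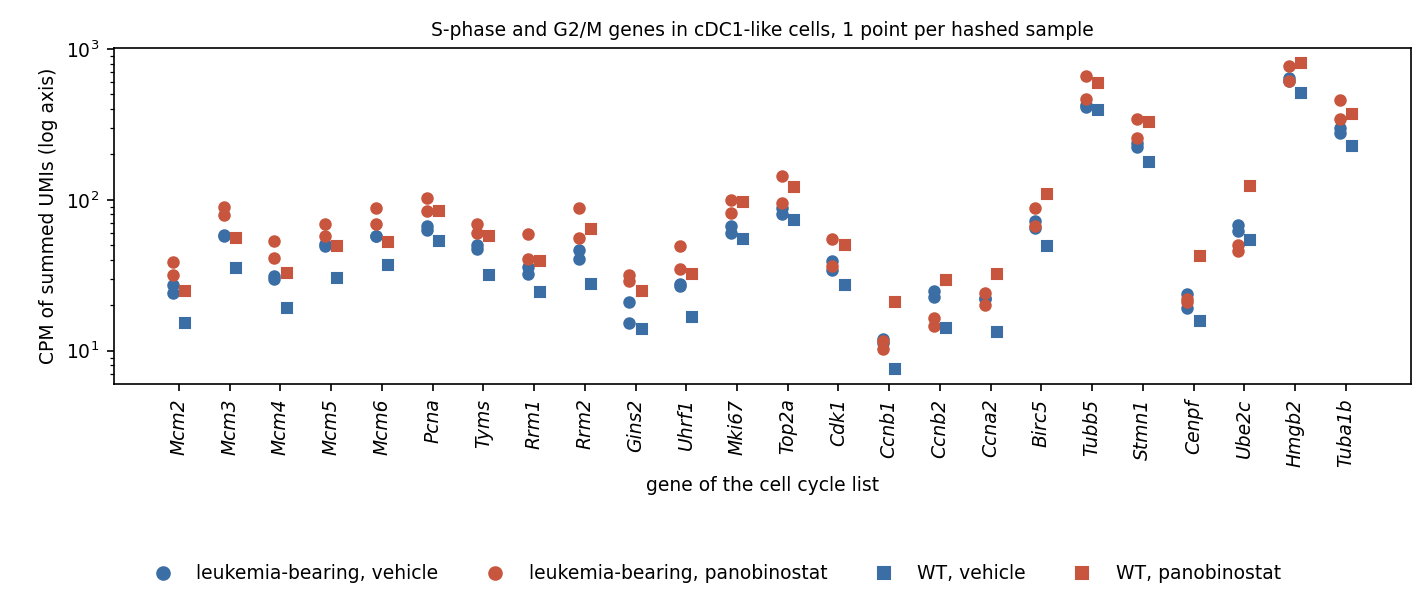
CPM (log axis) of the 24 S and G2/M genes in cDC1-like cells, 1 point per hashed sample. Rrm2 rose by 0.92 and Mki67 by 0.63 on the log2 scale with panobinostat.

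In all, 275 genes rose and 109 fell in cDC1-like cells among 9769 tested. Serpinb1a, an inhibitor of neutrophil proteases (ENSMUSG00000044734, chromosome 13, 32842092 to 32851185), rose by 1.93 (SE 0.13, adjusted p = 7.4e-08), from 12.1, 12.7 and 8.46 CPM in the vehicle samples to 49.2, 60.8 and 26.2 CPM. Ccr2, a chemokine receptor of monocytes and DC precursors, rose by 1.38 (SE 0.16, adjusted p = 0.00011), and Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) by 0.97 (SE 0.098, adjusted p = 1.7e-05). Cd207, the lectin langerin, fell by 1.22 (SE 0.20, adjusted p = 0.0026) and Mmp23 by 2.25. Of 18 genes of the endoplasmic reticulum 8 rose and 0 fell (10 adjusted over the list alone), among them Pdia6 by 0.48 (SE 0.073, adjusted p = 0.0014) and Creld2 by 0.51 (SE 0.11, adjusted p = 0.0133) (camera adjusted p = 3.3e-10, and adjusted p = 0.453 with an estimated correlation). Of 13 MHC class I genes 3 rose (Calr by 0.33, Pdia3 by 0.31 and Psmb8 by 0.22; camera adjusted p = 0.0314, and adjusted p = 0.453 with an estimated correlation). Of 13 chemokines Ccl4 rose by 0.87 and Il1b by 0.63 (camera adjusted p = 0.0099, and adjusted p = 0.583 with an estimated correlation). Neutrophil marker RNA stood at 22.4 CPM in the WT panobinostat cDC1-like cells and at most 2.97 CPM in the others, and acinar RNA at 424 CPM in WT vehicle and at most 7.93 CPM in the others.

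ISGs moved in both directions in cDC1-like cells: of 32 measured, Ly6a, Ifi27l2a (0.51), Zbp1 (0.55) and Ifitm3 (0.33) rose, while Slfn5 fell by 0.52 (adjusted p = 0.0123) and Parp14 fell by 0.48 (adjusted p = 0.041). The list as a whole was not called (camera adjusted p = 0.342). Single members of other lists moved: Socs3, a brake on cytokine signalling, rose by 1.13, Atf3 by 0.60, the sensor adaptor Tmem173 by 0.52 and the metallothionein Mt1 by 0.41. Ciita fell by 0.27, the checkpoint ligand Vsir fell by 0.33, Jun fell by 0.32 and Cbfa2t3 fell by 0.30. The count of 384 genes went to 117 by DESeq2, 34 after thinning and 175 in leukemia samples alone, and ran from 46 to 514 with each hashed sample left out.

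In pDC-like cells few genes changed with panobinostat. Of 9222 tested, 14 rose and 4 fell, with 622 at unadjusted p under 0.05. Slpi, a protease inhibitor, rose by 1.17 (SE 0.16, edgeR adjusted p = 0.00017), Pir by 0.99 (adjusted p = 9.7e-05), Socs3 by 0.78 (SE 0.15, adjusted p = 0.0114) and Fos by 0.34 (adjusted p = 0.0055). Vim, an intermediate filament protein, fell by 0.88 (SE 0.15, adjusted p = 0.0032). The largest values belonged to antibody genes of plasma cells, Iglc1 at 6.36 (SE 0.80, adjusted p = 5.8e-05) and Jchain at 4.67 (adjusted p = 0.00023). In WT panobinostat 1 of 34 cells held 2561 of 2569 Iglc1 UMIs, and plasma marker RNA stood at 4928 CPM in that sample and at most 35.5 CPM in the others. Jchain is itself among the plasma markers. Of 35 ISGs 0 rose and 0 fell (2 rose adjusted over the list alone; camera adjusted p = 0.183), and of 12 MHC class II genes 0 changed (3 adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.724 with an estimated correlation). DESeq2 called 2 of the 18 changed genes, and another split of the 6 samples gave 33 genes by edgeR.

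In cDC2-like cells 55 genes rose and 19 fell among 9181 tested. Single chemokine and early response genes rose (2 of 11 and 3 of 15 of these lists, and Ccl2 outside them): Ccl2, which draws monocytes, by 2.11 (SE 0.32, edgeR adjusted p = 0.0020), Cxcl9 by 0.99 (SE 0.15, adjusted p = 0.0014), Il1b by 0.46 (adjusted p = 0.011), Atf3 by 0.91 (adjusted p = 0.0034), Dusp1 by 0.45 (adjusted p = 0.011) and Fos by 0.42 (adjusted p = 0.0291). Ifitm1, an antiviral membrane protein, rose by 1.01 (SE 0.089, adjusted p = 2.2e-06) and Serpinb1a by 1.29 (adjusted p = 0.0065). Lyz2, lysozyme of myeloid cells (chromosome 10, 117277331 to 117282321), fell by 2.31 (SE 0.30, adjusted p = 0.00044). A Lyz2-high cluster held 17.0 and 18.5% of cDC2-like cells in leukemia vehicle, 8.78 and 7.30% in leukemia panobinostat, 2.84% in WT vehicle and 6.67% in WT panobinostat. Fn1, fibronectin, rose by 5.37 (SE 0.70, adjusted p = 0.00044) from values of 1.20, 2.59 and 0.272 CPM to 14.2, 1.14 and 42.8 CPM. Mmp9, a gelatinase abundant in neutrophils, rose by 1.71 (SE 0.24, adjusted p = 0.00077). Neutrophil marker RNA stood at 18.3, 14.1 and 22.1 CPM in vehicle and 19.7, 36.9 and 59.0 CPM in panobinostat samples. Mmp9 is itself among these markers, so this sum is not separate from its rise.

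By list in cDC2-like cells, 3 of 15 immediate early genes rose (8 adjusted over the list alone; camera adjusted p = 7.9e-08, and adjusted p = 0.189 with an estimated correlation). Of 11 chemokines and cytokines 2 rose (6 rose and 2 fell over the list alone; camera adjusted p = 0.00025, and adjusted p = 0.189 with an estimated correlation). The 14 cytokine receptors had 0 changed genes (2 rose and 4 fell over the list alone) and moved down (camera adjusted p = 0.00056, and adjusted p = 0.189 with an estimated correlation). MHC class I genes moved up with 0 of 13 past the threshold (1 over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.284 with an estimated correlation), and genes of the endoplasmic reticulum with 0 of 18 (3 over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.588 with an estimated correlation). Of 38 ISGs 1 rose, Ly6a by 0.75 (2 over the list alone). The count of 74 genes went to 18 by DESeq2, 22 after thinning, 10 at Leiden resolution 0.5, 7 with the ratio hashtag call and 147 in leukemia samples alone, and ran from 17 to 162 with each hashed sample left out.

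In mature DC-like cells 19 genes rose and 8 fell among 9483 tested. Ccl22, a chemokine that attracts regulatory T cells (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699), rose by 0.98 (SE 0.12, edgeR adjusted p = 0.0053), Cd69, an activation marker, by 0.93 (adjusted p = 0.0268), and Lgals1, the lectin galectin-1, by 1.29 (SE 0.19, adjusted p = 0.0119). The antibody gene Iglc3 fell by 1.86 and the clock gene Dbp fell by 1.30. Chemokines moved up as a list with 1 of 15 past the threshold (6 over the list alone; camera adjusted p = 5.6e-07, and adjusted p = 0.174 with an estimated correlation). So did the 13 MHC class I genes, with 0 past it (6 over the list alone; camera adjusted p = 1.7e-06, and adjusted p = 0.372 with an estimated correlation). Also called up were 13 costimulation genes with 0 past the threshold (4 higher and 1 lower over the list alone; camera adjusted p = 0.00061, and adjusted p = 0.372 with an estimated correlation), 16 apoptosis genes with 0 (4 over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.282 with an estimated correlation), 24 cell cycle genes with 0 (0 over the list alone; camera adjusted p = 0.00061, and adjusted p = 0.690 with an estimated correlation) and 12 MHC class II genes with 0 (0 over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.691 with an estimated correlation). Another split of the 6 samples gave 37 genes, DESeq2 gave 13, and the count ran from 8 to 112 with each hashed sample left out.

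**Figure D4:**
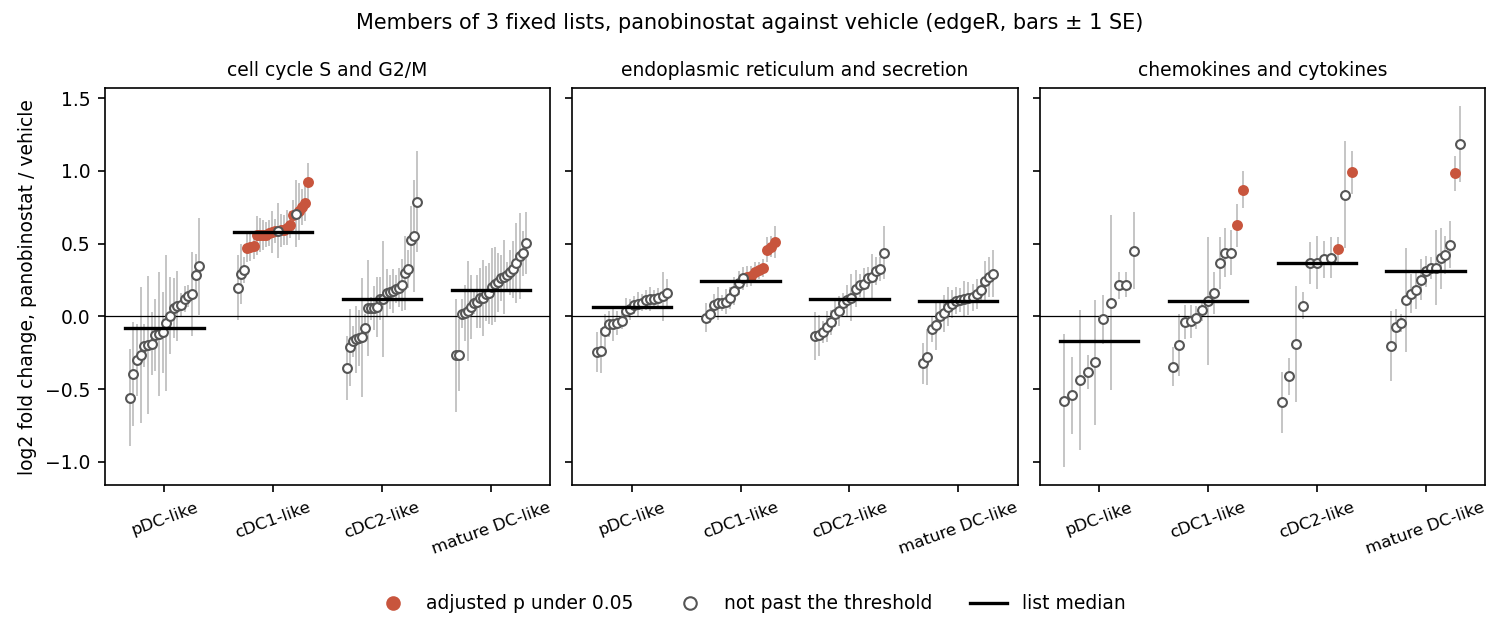
Log2 fold change with panobinostat (± 1 SE) of cell cycle, endoplasmic reticulum and chemokine genes in the 4 classes; filled points have an adjusted p under 0.05 and the black line is the list median. In cDC1-like cells 19 of 24 cell cycle genes are filled, with a median of 0.58. The cDC2-like cells leave out an unnamed cluster that joined raised cDC2 markers with cell cycle genes.

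Of the genes reported to rise when deacetylases are inhibited, at most 1 passed the threshold in a class. Past it were 0 of 12 in pDC-like, 1 of 11 in cDC1-like (Mt1, 0.41), 0 of 10 in cDC2-like (median 0.32, 7 positive, 5 rose adjusted over the list alone; camera adjusted p = 0.00063, and adjusted p = 0.189 with an estimated correlation) and 0 of 11 in mature DC-like cells. No gene of the deacetylase and acetyltransferase lists passed the edgeR threshold in any class.

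In the edgeR fits the ISG list stood higher in leukemia-bearing than WT samples, with the most genes called in cDC1-like cells. In cDC1-like cells 22 of 32 ISGs were higher and 0 lower (26 adjusted over the list alone), all 32 with a positive log2 fold change (median 0.62): Rsad2, the antiviral enzyme viperin (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), by 2.56 (SE 0.38, edgeR adjusted p = 0.00013), Isg15, a ubiquitin-like modifier, by 1.19 (SE 0.14, adjusted p = 1.1e-05), and Ly6a by 1.18 (SE 0.10, adjusted p = 4.9e-07). Ifi27l2a (ENSMUSG00000079017) was higher in cDC1-like (1.09, SE 0.090, edgeR adjusted p = 2.4e-07), pDC-like (0.59, adjusted p = 2.0e-05), cDC2-like (0.69, adjusted p = 0.0393) and mature cells (0.78, adjusted p = 0.0031). Its difference in cDC2-like cells varied with treatment (interaction −1.13), with 1 WT sample per treatment. In pDC-like cells 4 of 35 ISGs were higher (11 over the list alone; Ifi44 0.77, Lgals3bp 0.60), in cDC2-like cells 2 of 38 (14 over the list alone; Bst2 0.50), and in mature cells 5 of 34 (10 over the list alone; Ifit1 1.41, Isg15 0.77). None was lower. Camera gave adjusted p = 1.1e-25, 1.3e-14, 1.7e-19 and 1.9e-10 in cDC1-like, pDC-like, cDC2-like and mature cells, and adjusted p = 0.2297, 0.274, 0.255 and 0.0712 with an estimated correlation. Per hashed sample, pDC-like cells thinned to 2000 UMIs held medians of 9, 10.5, 9 and 8 ISG UMIs in leukemia and 7 and 7 in WT, cDC1-like cells 2 in each leukemia and 1 in each WT sample, cDC2-like cells 5.5, 6, 5 and 4 in leukemia and 4 and 4 in WT, and mature cells 2 in every sample. The ISGs called in cDC1-like cells went from 22 to 10 without WT vehicle, 13 by DESeq2 and 5 of 19 tested after thinning. In cDC2-like cells the 2 called went to 0 without WT vehicle (median 0.12, from 0.45), without leukemia vehicle 1, without leukemia panobinostat 1, by DESeq2, at Leiden resolution 0.5 and with the ratio hashtag call. They went to 14 without leukemia panobinostat 2, 10 without WT panobinostat and 8 with no filter on low counts. Over the settings the calls ran from 0 (without WT vehicle) to 6 in pDC-like cells and from 0 (doublets in the clustering) to 8 in mature cells. Within cDC2-like cells the Lyz2-high cluster held 7.30 to 18.5% in leukemia and 2.84 and 6.67% in WT, and a cluster of mixed markers 0 to 1.63% and 6.29 and 5.13%. Without these clusters the list median was 0.29, with 1 ISG called.

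Part of the immediate early and heat shock list was lower in leukemia, and the list call was lost with an estimated correlation. Camera gave adjusted p = 3.8e-12, 6.9e-11, 1.7e-11 and 1.7e-10 in cDC1-like, pDC-like, cDC2-like and mature cells, and adjusted p = 0.2297, 0.274, 0.255 and 0.123 with an estimated correlation. In cDC1-like cells 10 of 15 fell and 1 rose (12 and 1 over the list alone), in pDC-like cells 6 fell and 1 rose (7 and 1 over the list alone), and 3 of 15 fell in each of cDC2-like (5 over the list alone) and mature cells (8 over the list alone), all 3 heat shock genes. Hspa1a, an inducible heat shock protein (chromosome 17, 34969190 to 34972156), was at −0.78 in cDC1-like (adjusted p = 8.3e-05), −1.49 in pDC-like (adjusted p = 0.0020), −1.18 in cDC2-like (adjusted p = 0.0011) and −0.83 in mature cells, and Nr4a1 was at −0.82 (adjusted p = 2.7e-05) in cDC1-like cells. The Hspa1a difference depended on treatment in each class (interaction −0.72, adjusted p = 0.0090 in cDC1-like, −2.35, adjusted p = 0.0014 in pDC-like, −1.34, adjusted p = 1.1e-07 in cDC2-like and −0.68, adjusted p = 0.0337 in mature cells), with 1 WT sample per treatment. The interaction of early genes ran the other way, in 7 of the list in cDC1-like cells (0.62 to 1.90; Egr1 the highest, adjusted p = 8.8e-06), 4 in cDC2-like cells (0.58 to 0.96) and 2 in mature cells (Jun 0.71, Fosb 0.74). Of these 7, the 4 called lower in cDC1-like cells lost the call without WT vehicle: Atf3 went from −0.69 to −0.29, Junb from −0.55 to −0.18, Zfp36 from −0.46 to −0.018 and Fosb from −0.36 to 0.0051. This list is also raised by tissue handling, and the WT samples are 2.

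**Figure D5:**
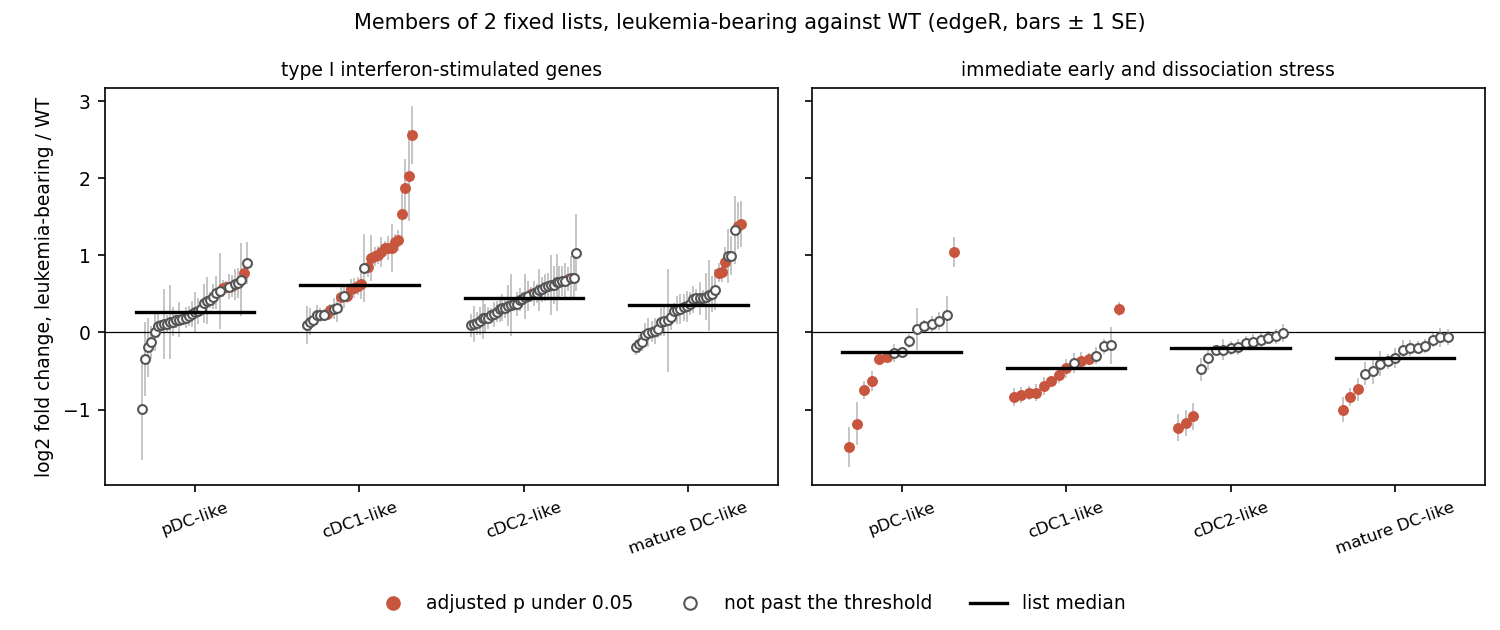
Log2 fold change of leukemia-bearing over WT (± 1 SE) of interferon-stimulated and immediate early genes in the 4 classes; filled points have an adjusted p under 0.05 and the black line is the list median. The interferon-stimulated list has a median of 0.62 in cDC1-like cells.

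Other lists also differed with leukemia. MHC class II genes were lower in pDC-like cells in 2 of 12 (8 over the list alone; H2-DMb2 −0.66, adjusted p = 0.0011; H2-Aa −0.25; camera adjusted p = 6.7e-09, and adjusted p = 0.427 with an estimated correlation). They were also lower in cDC1-like cells in 3 of 12 (6 over the list alone; camera adjusted p = 0.0097, and adjusted p = 0.494 with an estimated correlation), and went the other way in cDC2-like cells, with 1 of 12 higher (6 over the list alone; camera adjusted p = 0.0050, and adjusted p = 0.255 with an estimated correlation). In cDC1-like cells 8 of 24 cell cycle genes (11 higher and 1 lower over the list alone), 7 of 18 genes of the endoplasmic reticulum (8 over the list alone) and 5 of 12 glycolysis genes (7 over the list alone) were higher and 0 lower (camera adjusted p = 9.4e-05, 9.4e-05 and 0.0021, and adjusted p = 0.494, 0.494 and 0.2297 with an estimated correlation). The cycling cluster held 8.37% of cDC1-like cells in WT vehicle, 22.9% in WT panobinostat and 17.4 to 23.6% in the leukemia samples. In that share WT vehicle alone stood below the leukemia samples, so the cell cycle difference may rest on that sample. Also in cDC1-like cells, Il1b (−1.30, edgeR adjusted p = 7.1e-06), Ccl5 (−0.96) and Cd80 (−0.88) were lower and Cd40 (0.53) and Cxcl9 (0.59) higher. In mature cells 6 of 15 chemokines and cytokines were higher and 1 lower (6 and 1 over the list alone; camera adjusted p = 1.7e-10, and adjusted p = 0.0712 with an estimated correlation). Among them Ccl3 (1.95), Ccl4 (2.10) and Il1b (1.27) were higher, but under the ratio hashtag call they stood at −0.30, −0.22 and −0.064. The counts of higher and lower genes were 25 and 29 in pDC-like, 511 and 646 in cDC1-like, 25 and 23 in cDC2-like and 102 and 43 in mature cells; DESeq2 gave 4, 478, 15 and 82 in all. The comparison was planned as a covariate alone and rests on 2 WT samples, and with each hashed sample left out the counts ran from 15 to 78, 411 to 1277, 5 to 175 and 72 to 189.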

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

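The tests of the cycling cluster, of thinning, of the cells holding Iglc1, of the Siglec-H antibody and of other sample splits had predictions written before they were run, and the test of the hashtag call had its prediction written after the value was seen; all were chosen after the results they bear on were seen, and the conditions on pairs of samples and on the lower quartile were added later. Dixon's gap test was run on 18 measures over the 6 hashed samples, which mix conditions, and passes by chance in about 1 of 20.

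The median UMI count of leukemia vehicle 2, 13012 per kept cell, stood apart from the other 5 samples. Clusters with medians of 13690, 19398 and 17194 UMIs held 22.0, 23.1 and 11.4% of that sample, against at most 6.14, 1.37 and 7.41% of any other. Among pDC-like cells, 304 held 1662200 UMIs in that sample and 1140 held 6163000 in leukemia vehicle 1, which are like totals per cell. The higher median therefore followed at least in part from which cells the sample held. Shares with panobinostat over vehicle went up in every leukemia sample and down in WT for cDC2-like cells (ratio in leukemia 2.88 of kept cells and 1.94 of DC-like cells) and mature DC-like cells (2.04 of kept cells); these differences were not tested. An interaction test in edgeR, in which the WT change is 1 sample against 1 and has no replicate of its own, called 12, 56, 42 and 29 genes in pDC-like, cDC1-like, cDC2-like and mature DC-like cells whose panobinostat change differed between leukemia and WT. Among the genes named for panobinostat these were Iglc1 (log2 difference, leukemia minus WT, −7.44) and Jchain (−7.15) in pDC-like cells, Cenpf (−1.41), Birc5 (−0.97), Il1b (1.10) and Atf3 (0.80) in cDC1-like cells, Fos (0.58) and Lyz2 (−2.56) in cDC2-like cells, and Lgals1 (−1.11), Ryr3 (1.48) and Iglc3 (2.44) in mature DC-like cells. Genes named for leukemia against WT were also called, among them Hspa1a in pDC-like (−2.35), cDC1-like (−0.72), cDC2-like (−1.34) and mature (−0.68) cells, H2-Aa (0.43) in pDC-like, Ccl5 (0.77) in cDC1-like and Ifi27l2a (−1.13) in cDC2-like cells. The counts also hold genes of other cell types. In cDC1-like cells these include acinar genes such as Cela3b (12.5), Cpb1 (10.5) and Ctrb1 (8.31), where acinar RNA stood at 424 CPM in WT vehicle. Antibody genes were called as well, with Igha (−10.7) in pDC-like and Ighg3 (−4.74) and Igkc (−2.74) in mature cells.

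The lower pDC-like share of DC-like cells with panobinostat was weighed against loss at the hashtag call and against treated pDC-like cells being clustered elsewhere. With the ratio hashtag call the panobinostat over vehicle ratio in leukemia was 0.475 (pairs of samples 0.247 to 0.888). The lower share therefore did not depend on which call was used. Both calls gave the same single tag to 18578 barcodes, and barcodes that neither call kept are not covered. Loss at the hashtag call under both therefore stays open. The Siglec-H antibody took no part in clustering. Cells with a high count of it gave a ratio of 0.449 (pairs 0.282 to 0.752) outside the erythroid-like and unnamed clusters. But such cells could sit in the unnamed ones, and over all kept cells the ratio was 0.553 with pairs from 0.266 to 1.80. Clustering of treated pDC-like cells elsewhere therefore stays open as well. High cells covered 32.9% of pDC-like cells, and 83.4% of them were pDC-like. A loss of pDC-like cells with the drug is the biological reading the design offers. The exact permutation p of 0.2 from 3 against 3 samples, a test that leaves out disease state, does not establish it. Neither that loss nor uneven recovery in the enrichment was tested further.

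The rise of cell cycle genes in cDC1-like cells was weighed against a larger cycling cluster and against larger UMI totals. Without the cycling cluster the list median was 0.46 (lower quartile 0.27), and after thinning to 2000 UMIs it was 0.52 (lower quartile 0.46). Neither that cluster nor UMI totals therefore account for the whole of it. The list genes were kept out of the clustering, so cycling cells may also lie outside that cluster. A larger share of cycling cells among all cDC1-like cells therefore stays open. With the real grouping 384 genes passed in cDC1-like cells and the highest other split of the 6 samples gave 3 (1 of 10 splits reached the real count, the real one itself), but 10 splits are too few for a share under 0.05. The same count was 74 against 2 in cDC2-like cells (1 of 10), 18 against 33 in pDC-like cells (2 of 10) and 27 against 37 in mature DC-like cells (2 of 10). A change in dividing cDC1 with the drug is the biological reading, and a difference between animals is not excluded by it.

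The rise of Iglc1 and Jchain in pDC-like cells was weighed against a few cells carrying plasma cell RNA. In WT panobinostat 1 cell of 34 held 99.7% of the Iglc1 UMIs (2561 of 2569) and all 228 Jchain UMIs, with a doublet score of 0.031, and the rise of Jchain in this fit is therefore the content of that cell. Iglc1 was also higher in leukemia panobinostat (68.8 and 135 CPM) than in leukemia vehicle samples (19.0 and 23.2 CPM), and its log2 change was 2.12 at the lowest with a hashed sample left out. No biological explanation was tested.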

How the results depend on the processing

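Of the named genes, 1160 gene and setting combinations for panobinostat kept direction and call, 664 kept the direction alone and 5 reversed; for leukemia against WT these were 1814, 708 and 18, and for list genes between classes 1415 kept the call, 35 lost it, 22 gained one and 15 reversed. The alternatives tried differ between these groups, so the tallies do not rank them. The settings with a replicate block, leukemia samples alone, thinning before edgeR, the ratio hashtag call in edgeR, removed clusters and the spread without Ly6a and Ifi27l2a were chosen after seeing the data. In WT panobinostat the pDC-like comparison rests on 34 cells and 184850 UMIs. At the depth of each class edgeR recovered 31.3 to 68.7% of 1.5-fold changes in data simulated with a common dispersion for all genes. Leaving out a WT sample leaves 1 WT sample, which is assumed to vary like the other groups, and then takes the panobinostat change from the leukemia samples alone. Unless stated, the cause of a change was not tested.

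Shares of kept cells (cDC1-like, cDC2-like and mature DC-like) moved to 18.3, 20.3 and 14.5% with 200 genes and 20% mitochondrial UMIs, 11.7, 22.5 and 15.3% with 1000 genes and 5%, 12.7, 12.3 and 8.34% with doublets kept (pDC-like 19.5%), 12.1, 21.5 and 11.7% at Leiden resolution 2, 14.98, 17.6 and 17.3% with 15 principal components and 11.4, 21.1 and 8.26% with list genes in the clustering; at resolution 0.5 cDC2-like moved to 20.4% and mature to 18.6%. The Siglec-H ratio was 3.05 as a share of antibody UMIs, and the ISG spread in pDC-like cells 103% without Ly6a and Ifi27l2a. With doublets kept, 73 list genes were lower in pDC-like than cDC2-like cells and 52 lower than in cDC1-like cells.

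Between classes, reversed log2 ratios were Mt1 with doublets kept (0.83 against cDC2-like, 0.63 against cDC1-like cells), Rrm2 (0.21) and Cenpf (0.55) in pDC-like over cDC1-like cells with list genes in the clustering, and, in cDC1-like over cDC2-like cells, Rrm2 at −0.20 (200 genes), −0.46 (resolution 0.5), −0.52 (15 components) and −4.07 (list genes), Ccna2 at −0.47 (200 genes), −0.23 (1000 genes), −0.70 (resolution 0.5), −0.040 (resolution 2), −0.78 (15 components) and −3.99 (list genes), and Hdac6 at −0.050 (list genes).

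Genes past the threshold for panobinostat, in pDC-like, cDC1-like, cDC2-like and mature cells, were 2, 117, 18 and 13 with DESeq2, 6, 34, 22 and 43 after thinning to 2000 UMIs and 43, 639, 207 and 269 with no filter on low counts. With the ratio hashtag call cDC1-like gave 194, cDC2-like 7 and mature 69; with leukemia samples alone cDC1-like gave 175 and cDC2-like 147; with named clusters removed 185 and 133; with doublets in the clustering pDC-like 3 and mature 9; at resolution 0.5 cDC2-like 10. With each hashed sample left out they ran from 4 to 42, 46 to 514, 17 to 162 and 8 to 112, and the median change of the cell cycle list in cDC1-like cells from 0.43 to 0.73.

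For leukemia against WT the counts were 4, 478, 15 and 82 with DESeq2; 20, 349 and 25 after thinning in pDC-like, cDC1-like and cDC2-like cells; 90 and 27 at resolution 0.5 in pDC-like and cDC2-like cells; 140 and 9 with doublets in pDC-like and mature cells; 8 and 39 with the ratio call and 165 and 356 with no filter in cDC2-like and mature cells. With each hashed sample left out they ran from 15 to 78, 411 to 1277, 5 to 175 and 72 to 189, and the ISG list median from 0.23 to 0.53 (pDC-like), 0.46 to 0.72 (cDC1-like), 0.12 to 0.57 (cDC2-like) and 0.30 to 0.39 (mature).

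Reversed genes for panobinostat were Jchain in pDC-like cells (−0.048 without WT vehicle, −0.069 without WT panobinostat, −0.068 in leukemia alone; 5.74 at the highest), and with doublets in the clustering Crip1 (0.037, pDC-like) and Iglc3 (0.14, mature). For leukemia against WT, without WT vehicle, pDC-like Anxa2 was −0.0010 (highest 1.39), Vim −0.21 (1.24), Egr1 −0.41 (1.17), Cd209a 0.37 (lowest −0.72), Klf4 0.029 (−0.89), Irf4 0.43 (−1.09) and Gm47123 0.62 (−1.17), and cDC1-like Fosb 0.0051 (−0.71); without WT panobinostat, pDC-like Jchain was 0.069 (−7.15) and Iglc1 0.14 (−7.35). With doublets in the clustering Vim was −0.057 and Egr1 −0.30 (pDC-like), and Ccl4 −0.077 and Ccl3 −0.52 (mature); with the ratio call, mature Ccl4 was −0.22, Ccl3 −0.30, Il1b −0.064 and Igkc 0.23.

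With a replicate block on the tag numbers, mature cells gave 49 genes (39 higher, 10 lower), and pDC-like, cDC1-like and cDC2-like cells 17 and 4, 294 and 126, and 56 and 21 higher and lower. The labels do not say that equal numbers pair, and the correlation of same-number deviations was 0.033, 0.031, 0.012 and 0.076 in pDC-like, cDC1-like, cDC2-like and mature cells.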

Other observations

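The tests in this part were chosen after the results were seen. Some cell cycle genes of cDC1-like cells, picked after their values were seen, differed in how their panobinostat change compared between disease states. Mcm4, a helicase subunit of replication, stood at 29.6 and 31.1 CPM in leukemia vehicle, 41.2 and 53.4 CPM in leukemia panobinostat, and 19.0 and 32.8 CPM in WT vehicle and panobinostat, and Rrm2 at 40.3 and 46.8, 55.7 and 88.4, and 27.8 and 64.2 CPM. Ccnb2, a mitotic cyclin, stood at 22.8 and 24.8 CPM in leukemia vehicle, 14.5 and 16.5 CPM in leukemia panobinostat, and 14.1 and 29.2 CPM in WT (interaction −1.67, edgeR adjusted p = 0.00085), Ube2c, which targets cyclins for degradation, had an interaction of −1.65 (adjusted p = 2.1e-05), and Ccnb1 one of −1.57 (adjusted p = 0.0090). For Ccnb2 and Ube2c the fit over both states gave log2 changes of 0.20 (adjusted p = 0.702) and 0.29 (adjusted p = 0.507). The interaction was not called for Mki67, Top2a and Cdk1, which also mark dividing cells, and no test was made by phase. The WT side of each difference is 1 sample against 1.

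Among clusters that took no class, 2 expressed Ms4a2, a subunit of the IgE receptor, with Hdc and Car1, genes of basophil, mast cell and erythroid precursors. They held 22.0% and 23.1% of leukemia vehicle 2 against at most 6.14% and 1.37% of any other sample. That sample had the weakest hashtag, with a median own tag count of 88 against 345 to 768 in the others. Under the ratio hashtag call its single-tag barcodes went from 2937 to 1406. Whether the cells of these clusters belong to that sample was not tested. A cluster of 945 cells joined cDC1 markers with pancreatic acinar RNA such as Ctrb1, and made up 1.45, 1.01, 2.64, 5.80, 5.52 and 12.0% of the samples in the order leukemia vehicle 1 and 2, leukemia panobinostat 1 and 2, WT vehicle and WT panobinostat. Over all barcodes, with doublets and untagged ones, Ifnb1 had 14 UMIs, Ifna2 3 and Ifnk 2, and none of these lay in kept cells.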
